A study of Mus musculus with 6 samples.

How the data were processed

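Total RNA of KYSE30 cells was made into sequencing libraries with a SMARTer mRNA-seq kit, per the labels' protocols, from 3 Control samples and 3 samples exposed to 100 uM ACh for 4 h. One deposited table of the series gave, per gene, a value in each of the 6 libraries, a log2 fold change, a p-value and an adjusted p-value. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm10, and the labels give mouse as the organism. The table itself is of human genes. Of its 4195 gene IDs, 4183 start with ENSG, 229 genes lie on chromosomes 20 to 22, and the last gene on chromosome 1 ends at 246931967, beyond the last mouse gene on that chromosome at 195323493 in GENCODE M21. The human build and the counting tool are not given in the sources used here, so coordinates are printed as the file gives them. The counting is not stated to use strand, and reads of overlapping or antisense genes could not be told apart.

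The deposited values are a signal, normalised read counts made by the authors by dividing each library by one factor. This was read from the values, since every value in each library was a whole multiple, within 0.1 of a step, of one step per library between 0.768 and 1.13. Between 81 and 121 values per library lay at or under 20 steps. A step may be 1 read, but counts were not rebuilt from the values. No count test was run, although the design written before the data were examined had assumed counts. The log2 fold changes and the p-values in the table are the authors' own, per the file headers. All 4195 p-values were under 0.05, and the adjusted p-values at all 1823 ranks checked gave 11193 tests within 1, so the table holds only genes past that limit. The authors' deposited adjusted p was exactly 1 for 234 genes, whose mean values were at most 78.0. These were treated as not adjusted. The total depth of the libraries is unknown, and a normalised count of a few units rests on a few reads.

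Groups came from the labels. The values were tested on the log2(value + 1) scale with limma 3.58.1 (limma-trend, R 4.3.3), with group as the only term and Benjamini-Hochberg adjustment at 0.05 over the listed genes, without a filter. Fold changes are differences of group means on this scale. The added 1 shrinks the change of low genes. Uneven replicates can still make it larger than the authors' value, as for CHRNA10 (-1.61 against -1.38). Because the genes had been selected for a difference, limma calls nearly all of them, including 2677 of the 2678 past the authors' adjusted p. Passing both is thus nearly the authors' call alone, and limma on the same libraries is no independent support for it. The verbs rose and fell are therefore used only for genes past both limma and the authors' adjusted p of 0.05. The 234 low genes treated as not adjusted could not pass both, so for them a failure to pass is no result. On simulated data of 4195 genes with 200 changed, the limma test recovered 84 of 100 genes changed by 1.15-fold and 100 of 100 changed by 1.5-fold, with 8 false calls among 192. The simulated genes were not selected for a difference, shared a common dispersion and had no GC trend. Changes were planted only at means over 100. These rates therefore do not carry over to the listed genes.

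The lists were fixed before the data were examined, 38 in all. A list with at least 5 listed members was tested by a two-sided Fisher exact test of higher against lower members against the other listed genes, with Benjamini-Hochberg adjustment over 27 lists. Alternatives were camera with a preset correlation of 0.01 or an estimated one, fry, and, chosen after seeing the data, 10000 random lists matched on GC content and gene length, for the 24 lists in which at least 80% of members had a GC value. The named genes follow a rule fixed before the data were examined. It took the 8 largest rises and falls among called genes with a mean at or above the median of the listed genes (1194), a proper symbol and no overlap between the groups, up to 2 members per direction of each list described, and the cholinergic receptor subunits. COL1A1, LAPTM5 and EGFL7 were named because each was the only listed member of its list. A few genes that the rule names are not reported here.

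GC content was that of the longest protein-coding transcript of the mouse gene with the same symbol in GENCODE M21, because no human sequence was used here. It was found for 3676 of 4195 genes (87.6%) and 3674 of 3943 protein-coding genes (93.2%). The GC trend was removed per library by a local regression with a span of 0.3. Further alternatives were a pseudocount of 0.1, a lower-quartile filter, a replicate block, leaving out each library in turn, protein-coding genes without mitochondrial ones, a 2-fold minimum, and, chosen after seeing the data, equal totals over the listed genes, the authors' adjusted p and adjustment over 11193 tests. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9 were used.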

Results

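RNA was sequenced from KYSE30, an established human cell line from an esophageal squamous cell carcinoma. The cells were either left as controls or exposed to 100 uM acetylcholine (ACh), a neurotransmitter that acts through muscarinic and nicotinic receptors, for 4 h. Each group had 3 libraries. The question was which transcripts differ between stimulated and control cells at this time. The deposited table listed 4195 genes with normalised read counts per library, together with the authors' fold changes and p-values, and every listed gene had an unadjusted p under 0.05 in that table. Genes outside the table have no value here, so the statements below cover the listed genes. The listed genes summed to between 10519500 and 11469000 normalised reads per library. That sum is not the sequencing depth, which is unknown. If a step is 1 read, the factor that divided each library was 0.986 to 1.302 in Control and 0.884 to 0.954 in ACh. Every ACh library then had a smaller factor, and fewer reads in the listed genes, than every Control library. Nothing in the labels says that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

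Replicates resembled each other more than libraries of the other group. Across genes, Pearson's r of log2(value + 1) was 0.994 to 0.997 within groups and 0.979 to 0.983 between groups, and the first principal component held 73.5% of the variance and separated the groups. Listed genes do not represent all genes in this respect, because they were selected for a difference between the groups.

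IGFBP3, which encodes a binding protein for insulin-like growth factors, showed the largest rise among the genes with a mean at or above the median of the listed genes (1194) whose groups did not overlap. Its normalised count went from 1990 ± 122 in Control to 3119 ± 217 in ACh (SD, n = 3 each), a log2 fold change of 0.65 with a standard error of 0.05 (limma adjusted p = 6.24e-09). The gene, ENSG00000146674, lies on chromosome 7 from 45912245 to 45921874. NDRG1, a stress- and hypoxia-responsive gene on chromosome 8 (ENSG00000104419, 133237171 to 133302022), rose from 2127 ± 117 to 3137 ± 152 (SD, n = 3), a log2 fold change of 0.56. TXNIP, which encodes an inhibitor of thioredoxin, rose by 0.43 on the log2 scale, and the chromatin-associated genes TBL1XR1 and PHF6 each rose by 0.38. RPL21 rose by 0.45 and CHML by 0.36, and the processed pseudogene RPL7P9 was higher by 0.38. All of these passed both limma and the authors' adjusted p of 0.05.

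Among genes with a mean at or above the median of the listed genes, the largest falls were in transcripts of the translation machinery, in a mitochondrial transfer RNA and in ferritin. RPS23, a protein of the small ribosomal subunit (ENSG00000186468, chromosome 5, 82273358 to 82278577), went from 2707 ± 390 to 1421 ± 8.51 (SD, n = 3), a log2 fold change of -0.92 with a standard error of 0.07 (limma adjusted p = 3.92e-09). FTH1, the heavy chain of the iron store ferritin (ENSG00000167996, chromosome 11, 61959718 to 61967660), went from 63566 ± 3293 to 41683 ± 1529 (SD, n = 3), a log2 fold change of -0.61. The mitochondrial asparagine transfer RNA MT-TN went from 5035 ± 328 to 2459 ± 325 (SD, n = 3) and RPL35 from 27387 ± 2134 to 19260 ± 407 (SD, n = 3). The pseudogenes RPL39P3, RPS2P46, RPL6P27 and RPL18AP3 were lower by log2 fold changes of -1.11, -0.65, -0.49 and -0.47. Reads of such pseudogenes can belong to near-identical ribosomal protein genes, and the same holds for RPS23, RPL21 and FTH1, so these values are uncertain. The value of MT-TN is uncertain too, since reads of overlapping or antisense transcripts could not be told apart from its own.

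**Figure D1:**
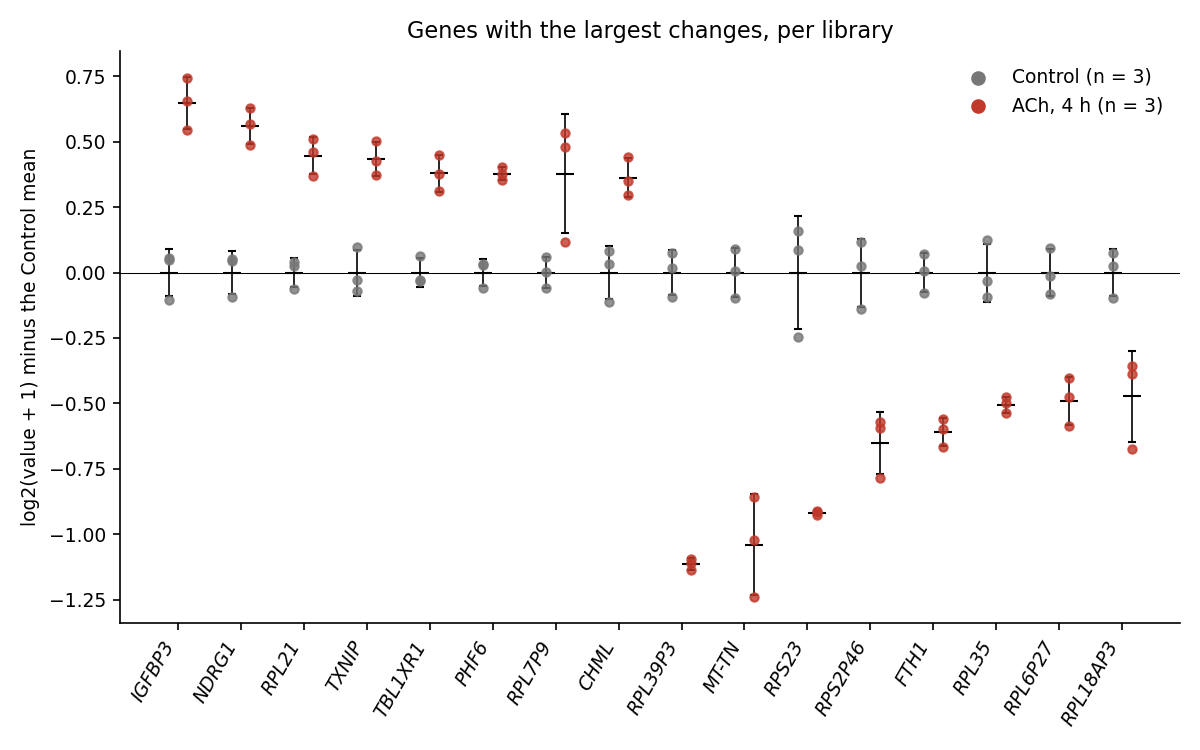
Each point is 1 library, as log2(value + 1) minus the Control mean of the gene; bars give the mean and SD of 3 libraries per group. The 8 genes on the left are higher in all ACh libraries and the 8 on the right lower, with log2 fold changes from 0.65 for IGFBP3 to -1.11 for RPL39P3.

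The changes were small. Of the 4195 listed genes, 2677 passed both tests, 1207 higher and 1470 lower in ACh, and 98.7% of these 2677 changed by less than 1.5-fold, with a median of 1.16-fold. The authors' deposited table held 7 genes with an adjusted p under 0.05 and a change of at least 2-fold, 3 higher and 4 lower. The limma test alone called 4178 listed genes, 2014 higher and 2164 lower (48.2% higher, exact 95% interval 46.7% to 49.7%), which follows from the selection of the table and is no count of changed genes in the transcriptome. The authors' adjusted p called 2678, of which 45.1% were higher. Scaling the libraries to equal totals over the listed genes turned the balance to 63.7% higher.

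Direction was tied to base composition. Over 3676 listed genes with a value, the Spearman correlation across genes between the log2 fold change and the GC content of the mouse gene of the same symbol was -0.76; genes are not independent replicates. Of the 368 genes with the lowest GC content 355 were higher in ACh (96.5%), and of the 368 with the highest 0 were. Chromosomes differed with it. On chromosome 19, 32 of 406 listed genes were higher (7.88%, median GC 58.0%), and on chromosome 13, 59 of 64 were higher (92.2%, median GC 45.1%), each against the other chromosomes with adjusted p = 5.64e-75 and 2.32e-13 by two-sided Fisher exact tests with Benjamini-Hochberg adjustment. With the GC trend removed from each library, 559 of the 3676 genes passed limma, against 3661 of the same genes with the trend kept. Of the 559, 475 had passed before with the same sign, and the others had the opposite sign or had not passed. Of the 2460 genes past both tests, 321 kept their call and sign. IGFBP3 and NDRG1 then stood at log2 fold changes of 0.76 and 0.67, RPL21 and TXNIP at 0.39 and 0.33, TBL1XR1, PHF6 and CHML at 0.17, 0.15 and 0.14, and RPS23, FTH1 and RPL35 at -1.09, -0.45 and -0.31. Of the named genes 70 had a GC value, of which 27 kept their call, 27 lost it in the same direction and 16 changed sign.

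**Figure D2:**
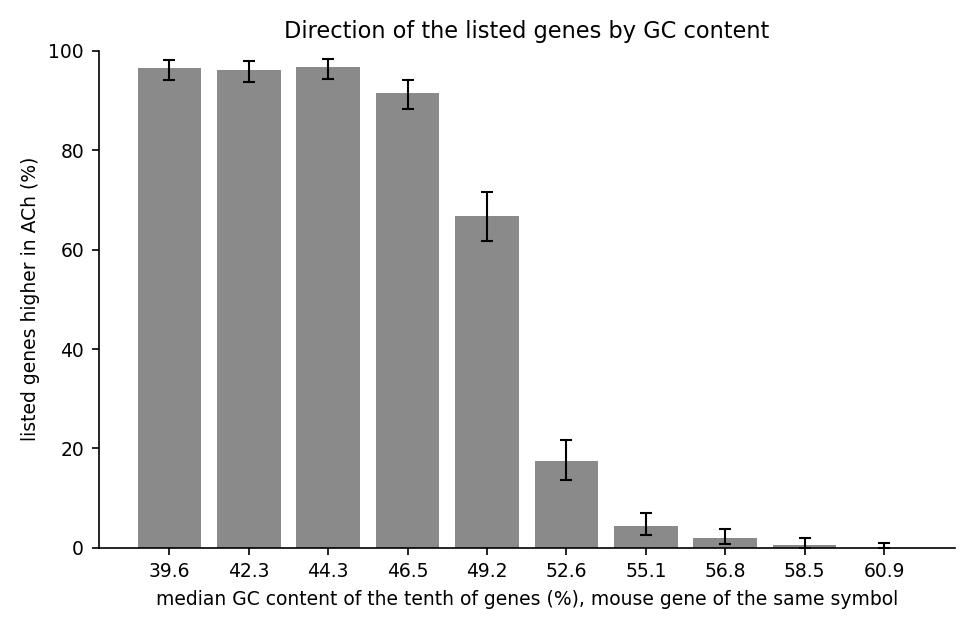
Bars give the share of listed genes higher in ACh for 10 equal groups of 3676 genes ordered by GC content of the mouse gene of the same symbol, with exact 95% intervals over genes. The share was 96.5% in the lowest group, 66.8% in the fifth and 0% in the highest.

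Ribosomal protein genes were mostly lower. Of the 73 genes fixed in this list 53 were listed, and 41 fell, 5 rose and 7 did not pass both tests. The list held more lower genes than the rest of the table (6 higher and 47 lower, two-sided Fisher exact test, adjusted p = 3.74e-07 over 27 lists). Its camera adjusted p was 3.72e-06 with the preset correlation, and the adjusted p was 0.61 with an estimated correlation. The median log2 fold change was -0.19, and beside RPL21, RPL9 rose by 0.14, which became 0.03 and lost its call with the GC trend removed. The median GC content of the list was 52.8%. With the GC trend removed 9 of the 53 members were higher (Fisher exact test, adjusted p = 6.75e-06) and 23 of the 46 calls were kept, while against random lists matched on GC content and length the adjusted p was 0.0854.

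Transcripts of the respiratory chain were lower. The mitochondrially encoded genes had been fixed as a sign of library or RNA quality, and this sign differed between the groups. All 10 listed mitochondrially encoded protein genes had lower means in ACh and 7 fell, with 3 not past both tests (Fisher exact test, adjusted p = 0.0183, and adjusted p = 0.61 by camera with an estimated correlation). MT-ATP8, a subunit of the ATP synthase, went from 261 ± 35.1 to 133 ± 20.2 (SD, n = 3), and MT-ND3, a subunit of complex I, had a log2 fold change of -0.35. The median GC content of the mouse genes of the same symbols, 36.0%, is that of genes that were otherwise higher. The GC content of the human mitochondrial genes was not measured. Of 22 listed nuclear genes for the respiratory chain, 15 fell, 1 rose and 6 did not pass both tests (adjusted p = 0.0129, and adjusted p = 0.61 by camera with an estimated correlation). CYC1 and NDUFA2, of complexes III and I, had log2 fold changes of -0.26 and -0.38, and COX6C rose by 0.13, a call that ended without ACh replicate 1 (0.0951). The median GC content of this nuclear list was 54.8%, and against lists matched on GC content and length its adjusted p was 0.889. After removal of the GC trend MT-ATP8, MT-ND3 and NDUFA2 kept their calls, CYC1 lost its call and COX6C changed sign. For the mitochondrially encoded genes this removal rests on the mouse GC content.

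Genes of mitosis were mostly higher, short of the threshold as a list. Of 19 listed members 14 rose, 1 fell and 4 did not pass both tests (Fisher exact test, adjusted p = 0.0654). The adjusted p was 0.0139 with equal totals and 0.0260 by camera with the preset correlation, and the adjusted p was 0.61 with an estimated correlation. ASPM, a spindle pole gene, and TOP2A, a topoisomerase of dividing cells, rose by 0.21 and 0.19 on the log2 scale, while the phosphatase gene CDC25B fell by 0.15. The list had a median GC content of 43.4%, and with the GC trend removed its median log2 fold change went from 0.18 to 0.03 and 0 of its 15 calls past both tests kept their sign and threshold by limma (0 at an unadjusted p under 0.05). Genes of DNA replication went both ways, with 4 of 18 listed members higher and 6 lower past both tests. RFC3 and RRM2 rose by 0.35 and 0.22, and MCM7 and MCM2 fell by 0.17 and 0.19. Of these 4 genes RFC3 alone kept its call after removal of the GC trend.

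Hypoxia-inducible and glycolytic genes went both ways. Of the 9 listed glycolytic enzymes 2 were higher in ACh, and of the 9 other listed members 8 were. Of 18 listed members 10 rose, 7 fell and 1 did not pass both tests, and the balance of directions did not differ from the other listed genes (Fisher exact test, adjusted p = 0.881). Beside NDRG1, the glucose transporter gene SLC2A3 rose from 96.7 ± 19.2 to 205 ± 36.3 (SD, n = 3). ALDOA, a glycolytic enzyme, went from 177 ± 27.5 to 97.3 ± 11.2 (SD, n = 3) and SLC2A1, another glucose transporter gene, had a log2 fold change of -0.19. The count of ALDOA was far below the Control means of the glycolytic genes ENO1 (62460) and TPI1 (13310). Reads of overlapping genes could not be told apart, so the value of ALDOA is uncertain. Against lists matched on GC content and length, but not on expression, the list stood 0.30 higher on the log2 scale, with adjusted p = 0.0048 over 24 lists. Camera gave an adjusted p of 0.819 with an estimated correlation. The listed genes were cut at p under 0.05, so changes near 0 are scarce. A median can then jump across 0 with the balance of signs. The list's median was 0.18, against -0.12 in the matched lists, and 0.08 with the GC trend removed. After removal of the GC trend 15 of the 18 members were above 0 (Fisher exact test, adjusted p = 0.0695). NDRG1, SLC2A3 and ALDOA then kept their calls and SLC2A1 lost its call.

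The one cholinergic receptor gene in the table was CHRNA10, a nicotinic subunit on chromosome 11 from 3665587 to 3671384 (ENSG00000129749). Its normalised counts were 27.6, 20.3 and 22.3 in Control and 2.14, 7.92 and 16.8 in ACh. At this level its limma log2 fold change of -1.61 (adjusted p = 0.0027) became -0.943 without ACh replicate 1. It was among the 234 low genes treated as not adjusted by the authors, so it could not pass both tests. Of the genes handling acetylcholine and choline 3 were listed. The choline transporter-like genes SLC44A2 and SLC44A1 had log2 fold changes of -0.15 and 0.14, and LYNX1, which encodes a modulator of nicotinic receptors, of -0.31. Among 11 listed immediate early genes 3 rose, 4 fell and 4 did not pass both tests. FOS went from 81.1 ± 5.54 to 115 ± 2.31 (SD, n = 3) with an adjusted p of 0.0496 in the authors' deposited table, KLF10 rose by 0.21, and JUND and JUNB fell by 0.28 and 0.19. The ligands of the epidermal growth factor receptor EREG and TGFA rose by 0.24 and 0.16. After removal of the GC trend FOS and TGFA kept their calls. KLF10, EREG, SLC44A2 and LYNX1 then lost theirs, and JUND, JUNB and SLC44A1 changed sign.

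Of 5 listed inflammatory targets of NF-kB, 3 rose, 1 fell and 1 did not pass both tests. PTGS2, the inducible cyclooxygenase, rose from 192 ± 28.9 to 289 ± 25.2 (SD, n = 3) and BIRC3 by 0.45 on the log2 scale, while NFKBIA, which encodes the inhibitor of NF-kB, fell by 0.16. Of 5 listed calcium, CREB and NFAT targets 2 rose, PDE4D by 0.24 and FOS by 0.50, and the other 3, PER1 among them with a log2 fold change of -0.21, did not pass both tests. The balance of directions in these lists did not differ from the other listed genes (adjusted p = 0.549 for each), and camera gave an adjusted p of 0.61 for each with an estimated correlation. Against lists matched on GC content and length their medians stood 0.24 and 0.38 higher on the log2 scale (adjusted p = 0.0192 and 0.0384), over few members and without matching on expression. For the calcium list this excess spans 0, from -0.14 in the matched lists to 0.24, and changes near 0 are scarce among the listed genes. With the GC trend removed the medians of the NF-kB and calcium lists were 0.23 and 0.21. The lower-quartile filter took all higher members out of the NF-kB list and left it at 0% higher. PTGS2, BIRC3, PDE4D and FOS kept their calls once the GC trend was removed, and NFKBIA lost its call, with a log2 fold change of -0.02.

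The lists of interferon-responsive genes and of antigen presentation and immune checkpoints did not pass. GC values existed for 11 of 14 and 8 of 11 of their members, under 80%, so a check for GC content is void for both. Of 14 listed interferon genes 5 fell, 1 rose and 8 did not pass both tests (adjusted p = 0.549), with IFI6 and ISG15 down by log2 fold changes of -0.32 and -0.24 and IFIT2 at 0.10. Of 11 checkpoint and antigen presentation genes 6 fell, 1 rose and 4 did not pass both tests (adjusted p = 0.258). HLA-C had a log2 fold change of -0.25, CD276 of -0.15 and CD47 of 0.30. Of 13 NRF2 targets, genes of the oxidative stress defence, 8 fell, 1 rose and 4 did not pass both tests (adjusted p = 0.607). GC values existed for 10 of these 13, also under 80%, so the check is void for this list as well. FTH1, described above, was among those that fell, and SLC7A11, a cystine transporter gene, had a log2 fold change of 0.20. Of the genes named in these lists, FTH1 and ISG15 kept their calls once the GC trend was removed and CD47 lost its call. IFIT2, CD276 and SLC7A11 changed sign, of which IFIT2 passed limma in the opposite direction (-0.10, adjusted p = 0.0221). IFI6 and HLA-C had no GC value.

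Heat shock genes and cholesterol synthesis genes went both ways. Of 15 heat shock genes 4 rose and 4 fell, with HSPB1 and HSPA1B at log2 fold changes of -0.33 and -0.27 and DNAJB4 and HSPA4 at 0.27 and 0.11. Of 12 cholesterol synthesis genes 4 rose and 6 fell, with IDI1 at 0.31 and PMVK and LSS at -0.30 and -0.16. Among 11 listed basal squamous genes 5 rose and 3 fell. TP63, a regulator of basal squamous cells, and DST rose by 0.23 and 0.21, and SOX2 and KRT15 had log2 fold changes of -0.20 and -0.17. The call of KRT15 ended without ACh replicate 2 (-0.0763). Of 7 YAP targets 3 rose, NT5E by 0.35 and F3 by 0.17, and AMOTL2 fell by 0.14. Of 6 neurotrophic and axon guidance genes, SEMA3A and NRP1 rose by 0.26 and 0.27 and ARTN, a ligand of the family of glial cell line-derived neurotrophic factor, had a log2 fold change of -0.33. Genes often used as references moved too. TFRC and HPRT1 rose by 0.17 and 0.28, and GAPDH and PPIA had log2 fold changes of -0.25 and -0.15. Of the genes in this paragraph, DST, SOX2, NT5E, NRP1 and PPIA kept their calls after removal of the GC trend, and TP63 and HPRT1 had no GC value. HSPB1, HSPA1B, DNAJB4, IDI1, PMVK, LSS, F3, SEMA3A, ARTN and GAPDH lost theirs, and HSPA4, KRT15, AMOTL2 and TFRC changed sign.

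**Figure D3:**
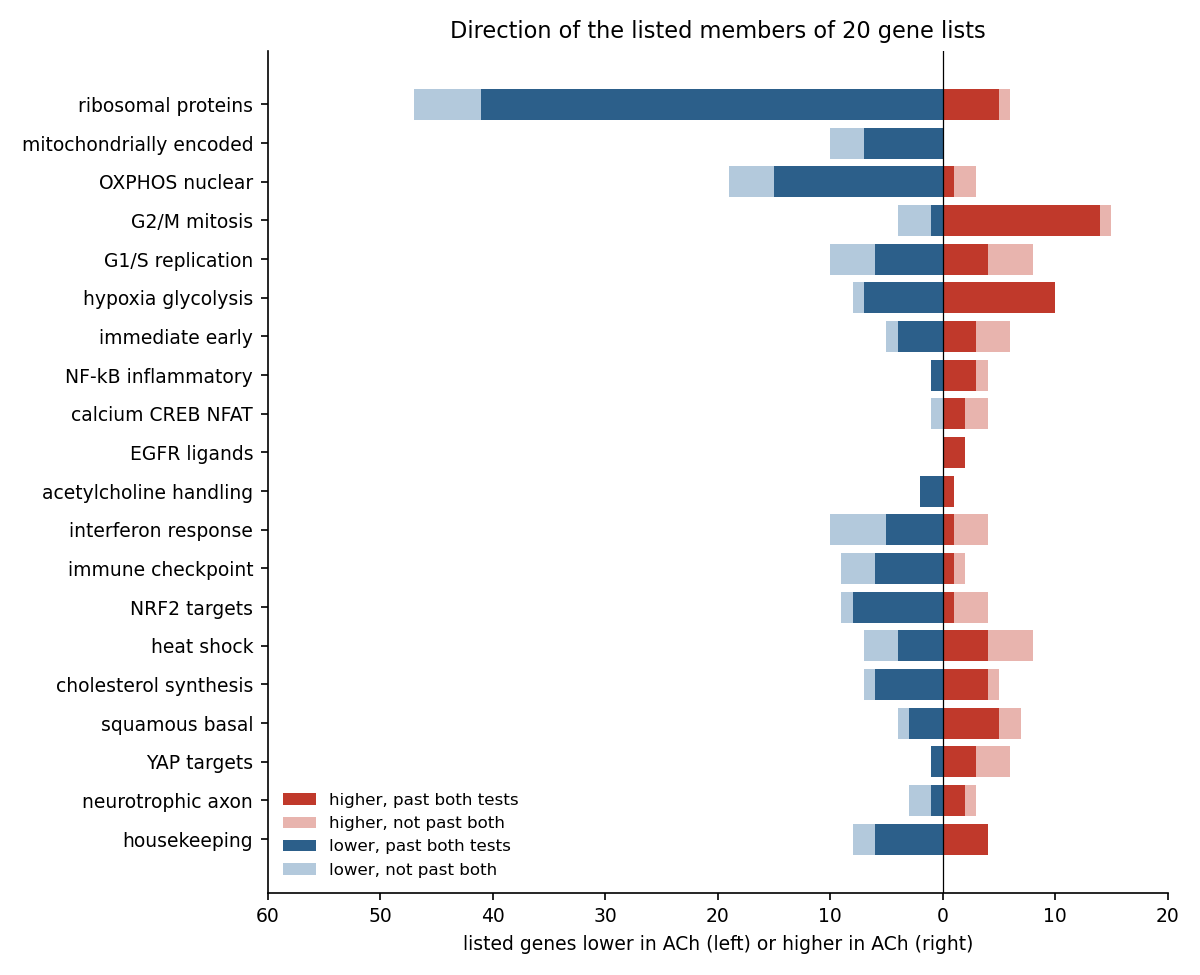
Bars count the listed genes of 20 lists that are lower (left) or higher (right) in ACh, dark where limma and the authors' adjusted p both passed 0.05 and pale otherwise. Ribosomal protein genes stand out with 47 lower and 6 higher.

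Of the 38 lists, 27 had at least 5 listed members, and 3 passed the Fisher exact test after adjustment, those of the ribosomal proteins and of both parts of the respiratory chain. With an estimated correlation camera passed 0 lists, and 0 at an unadjusted p under 0.05 (smallest adjusted p = 0.61), against 4 with the preset correlation and 16 by fry. Adjusted over the list alone, the number of limma calls was the same as over all listed genes in 37 lists and larger by 1 gene in the remaining list. None of the metallothionein or replication histone genes was listed. Of markers of other cell types, COL1A1 of fibroblasts, LAPTM5 of immune cells and EGFL7 of endothelium were the only members listed. EGFL7 fell by 0.28, and COL1A1, at -0.33, did not pass both tests. LAPTM5, at 0.96, was among the low genes treated as not adjusted by the authors and could not pass both. With the GC trend removed EGFL7 stood at -0.07 and lost its call.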

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

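The settings with the GC trend removed, or kept over the same genes, equal totals, the authors' adjusted p, the authors' number of tests and matched random lists were chosen after seeing the data, and the other alternatives before. The count of 4178 limma calls became 559 with the GC trend removed, 2678 by the authors' adjusted p and 139 with a 2-fold minimum, and lay between 3864 and 4037 when 1 library was left out. It was 4079 when adjusted over the authors' number of tests. The share of called genes that were higher, 48.2%, turned to 63.7% with equal totals and to 60.4% with a 2-fold minimum, moved to 46.3% with the lower-quartile filter, 41.9% with the GC trend removed and 45.1% by the authors' adjusted p, and was 47.5% to 48.8% with 1 library left out. The filter tested fewer genes and the 2-fold minimum called fewer of the same genes, by their construction. Equal totals scaled the ACh libraries up against the Control libraries, since every ACh sum over the listed genes was smaller than every Control sum. The median log2 fold change of the listed genes thereby moved from -0.0976 to -0.0176. For the other shifts the cause was not tested. In place of 3 lists, 0 passed camera with an estimated correlation and 16 passed fry, which does not compare a list with other genes. The lowest correlation within a group, 0.994, was 0.987 with a pseudocount of 0.1, which spreads the values of low genes. The log2 fold change of CHRNA10 was -0.943 to -2.19 with 1 library left out.

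The deviations of same-numbered libraries correlated across genes at 0.0821, 0.0555 and 0.0471. Differently numbered libraries were not compared, so whether the replicate numbers pair the samples cannot be told from these values. A replicate block gave 4187 calls.

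Of 82 genes that the rule names beside the receptor, 70 had a GC value. With the GC trend removed 27 kept their call, 27 lost it in the same direction and 16 changed sign. The latter were COX6C at -0.0188, TOP2A at -0.0114, CDC25B at 0.0199, PLK1 at 0.0817, JUND at 0.0191, JUNB at 0.0597, SLC44A1 at -0.0711, IFIT2 at -0.102, IFI44L at -0.0369, CD276 at 0.0341, SLC7A11 at -0.0157, GCLM at -0.0772, HSPA4 at -0.0540, KRT15 at 0.0101, AMOTL2 at 0.0532 and TFRC at -0.0538 on the log2 scale. Removal of the trend moves these values by its construction. IFIT2 alone of these 16 then passed limma, in the opposite direction (adjusted p = 0.0221). Equal totals ended the call of 10 named genes and leaving out 1 library that of 4, COX6C without ACh replicate 1, KRT15, NGFR and IFI44L without ACh replicate 2 and IFI44L also without Control replicate 3. The design's count-based alternatives (another size-factor scaling, a Wald test and voom weights) were not run because the deposited values are normalised and counts were not rebuilt, and no filter was the main setting. Depth limits the 234 genes with mean values up to 78.0.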

Other observations

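The test of glycolytic enzymes against other hypoxia genes and that of the better-expressed pseudogenes were set before their results were seen, and all other tests here were chosen after. By the authors' own transcription factor column, 62 of 89 listed zinc finger genes of the C2H2 family were higher, with 31 risen and 21 fallen past both tests (two-sided Fisher exact test against the other listed genes, adjusted p = 0.000633 over 11 families). On chromosome 19, 22 of 32 such genes were higher, 9 risen and 8 fallen past both tests, against 10 of 374 other listed genes there. A check of this for GC content is void, since 26 of the 89 and 3 of the 32 had a GC value. The 26 had a median GC content of 47.9%, at which most listed genes were higher, and a median log2 fold change of 0.03 with the GC trend removed. Basic helix-loop-helix factors were mostly lower, with 4 of 17 higher, short of the threshold (adjusted p = 0.280). Longer genes were higher more often, with a Spearman correlation across 4195 genes of 0.34 between log2 fold change and length, and 0.24 over 3676 genes after removal of the GC trend.

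The direction of the listed genes followed GC content, with a Spearman correlation across genes of -0.76, a value that describes the pattern and leaves open whether the GC content of the transcripts is its cause. The correlation was between -0.71 and -0.76 in each of the 9 pairs of 1 ACh and 1 Control library, while a library set against its own replicates gave -0.26 to 0.25. Gene length as the whole cause is argued against by a correlation of -0.73 with GC after the length trend was removed. By the mouse values, GC content alone does not account for the mitochondrially encoded genes, of which 0% were higher although that GC content is low. This holds if the human genes, whose GC content was not measured, also lie where most listed genes were higher. Whether the 2 groups were prepared as separate sets, which may give such a trend, cannot be told apart from a response to ACh that itself sorts by base composition, since 0 samples have a batch in their labels and any such set would coincide with the groups. The factors that divided the libraries also differed by group, if a step is 1 read. Whether this difference bears on the trend was not tested.

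Hypoxia-inducible genes stood higher than their base composition would give. No median of 10000 random lists matched on GC content and length reached that of the list (two-sided permutation p = 0.0002, the smallest they can give), which argues against GC content and length as the whole cause, although 15 of 18 members above the GC trend gave an adjusted p of 0.0695 by Fisher's exact test and camera one of 0.819 with an estimated correlation. The size of the excess is uncertain, since changes near 0 are scarce among the listed genes and the list's median was 0.18 before and 0.08 after removal of the GC trend. A common rise of hypoxia genes and glycolytic enzymes stays open, because the 9 listed glycolytic enzymes had a median of 0.0479 on the log2 scale after removal of the GC trend and the 9 other members one of 0.308 (two-sided exact permutation p = 0.114). Before that removal 2 of the enzymes and 8 of the other members were higher in ACh, and after it 7 and 8 lay above the trend. A response to ACh may underlie this, as may the density or oxygen supply of the cultures, and neither was tested.

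Processed pseudogenes were higher more often than protein-coding genes, with 71 of 97 against 1874 of 3943. Past both tests 14 rose and 10 fell, and 13 and 10 of these had a mean value of at least 100. Genes with mean values up to 78.0 were treated as not adjusted by the authors and could not pass both, so these counts say little about the low pseudogenes. In 37 pairs of a pseudogene and its listed parent gene, the pseudogene's log2 fold change exceeded the parent's by a median of 0.70, a value that rests in part on pseudogenes of very low counts. In the 16 pairs with a pseudogene mean of at least 100, the median excess was 0.149 and 9 pseudogenes lay above their parents (8 of 15 parents, two-sided exact sign test, p = 1). A constant share of the parent's reads in the pseudogene would give both the same fold change. Of the 37 pairs 17 had opposite signs, which argues against a constant share in those pairs, though some rest on very low counts. Because the 16 pairs differ in both directions, their median and sign test cannot decide, and a constant share stays open for the other pairs. Low read numbers also stay open as a candidate source, since of the 36 processed pseudogenes with a mean value of at least 100, 58.3% were higher (exact 95% interval 40.8% to 74.5%).

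The real grouping of the 6 libraries gave 4178 genes past the threshold, and the highest of the other 9 of the 10 splits gave 3, so 1 split reached that count. With 10 splits the share cannot fall under 0.05, and the genes had also been selected for the real grouping.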
